A study of Mus musculus with 6 samples.

How the data were processed

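Total RNA from the brains of 3 WT and 3 APP/PS1 male mice aged 9 months was measured; the labels call the replicates of each genotype biological. Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was removed, and fluorescent cRNA labelled with Cy3 was made by random priming. Per the file headers, the scanner files hold spot intensity, with a background-subtracted processed signal, from Agilent Feature Extraction (version 11.0.1.1 per the submitters' processing notes), on an array built for the mm9 genome. The value table deposited by the authors holds log2 values whose quartiles are equal in all columns, with a median of 7.06 in every column; how they were normalized and filtered is not given in the sources used here. Each of its columns for the 5 scanned arrays correlated with that array's log2 processed signal at 0.99965 or more, so the direction and scale of the table were taken as log2 signal, and genes were not centred. The table holds 79.2% of the 61194 non-control spots. No scanner file of WT replicate 3 was used here.

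Rows of the value table were tied to probes by spot number. Identifiers from RefSeq were matched to symbols through a gene table of GRCm38.p6, used only for names and gene order because the array build differs: 116 probes matched 112 genes, and 74 of these probes are in the value table. The other probes carry lincRNA, ultraconserved element, transcript or array maker's identifiers that the files used here do not pair with genes. 20 probes named as negative controls, of 60 spots each, were left out of tests.

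Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The design fixed before the data were examined was 3 against 3 samples on the value table. WT replicates 2 and 3 were averaged after their near-identity and the 3 against 3 count had been seen, because they differed by less than the spot noise, and both counts are given. The scanner signals were log2 processed signals minus each array's 75th percentile, with outlier spots left out, spots of 1 probe averaged and probes kept that were well above background on at least 2 of the 5 arrays. No spot of a tested probe was saturated. Where no array of a group measured a probe well above background, a bound is given: the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

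Named genes follow a rule fixed before the data were examined: transgene-related genes, the 10 largest rises and 10 largest falls past the threshold with groups that do not overlap, the leading members of each fixed list (an item of the rule is not reported here), and for lincRNA probes the 5 per direction with the smallest p at 2-fold or more. Lists with under 5 measured members are described by their members, and no set test was run. Where under 80% of the list genes with a probe have a table row, the scanner signals lead, as they do here. lincRNA probes were set against 1000 random sets of other probes matched on mean signal.

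On simulated data with 200 changed probes among 48436, the fit of 2 against 3 recovered 0% of the 2-fold changes and made 0 false calls, and the 3 against 3 fit recovered 57% of them with 6 false calls, 7.32% of its calls. A second simulation with 16000 changed probes was added after that result was seen. There the fit of 2 against 3 recovered 81.8% of the 2-fold changes and 61.2% of changes of 0.5 (log2), and 3.97% of its calls were false. The scanner fit, on 45560 probes, recovered 85.2% and 63.8% there and 0% of both sizes with 200 changed probes. Noise was drawn independently for each probe and sample, without a slide effect. For 3 against 3, WT replicates 2 and 3 were also drawn as independent, with a spread lowered by their near-identity. The false shares thus do not carry over to the real calls.

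Alternatives covered scaling, background, filters on dim probes, the variance model, the threshold, the replicate number as a block and each sample left out. Background correction by normexp used the median spot signal with an offset of 50, since the mean signal column is absent from the files used here. Samples with the same replicate number did not deviate together (correlations across bright probes 0.0439, -0.0961 and -0.0213). Slide and scan could not be used as a block, because each scanned slide held 1 genotype.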

Results

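RNA from the brains of male mice aged 9 months was compared between wild-type (WT) animals and APP/PS1 animals, a transgenic line in which amyloid plaques form. The labels describe 3 biological replicates per genotype. Each sample was hybridised in 1 colour (Cy3) to an array designed mainly for long non-coding transcripts. The value table held 48436 probes for all 6 samples, and scanner signals were used for 5 of them. Between 40592 and 46873 probes were well above background on the 5 scanned arrays, with the 3 APP/PS1 arrays at 41919, 45904 and 46873 and the WT arrays at 41248 and 40592. The small number of arrays limits the precision of every value.

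WT replicates 2 and 3 were nearly identical. After removal of position trends, their scatter over 18742 bright probes was 0.0297 (log2), against 0.0741 to 0.104 between APP/PS1 replicates and 0.089 between WT replicates 1 and 2. Repeated spots of 1 probe on WT arrays 1 and 2, where biology cancels, scattered by a median of 0.0563, and 13 of the 14 bright multi-spot probes scattered more than WT replicates 2 and 3 did. Among dim probes the scatter was 0.234 against a median of 0.386, with 1 of only 2 multi-spot probes above it. WT replicates 2 and 3 thus differed by less than the spot noise among bright probes and were counted as 1 sample, giving n = 2 for WT and n = 3 for APP/PS1.

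The central question of the design was which transcripts differ in the brain between the genotypes. Among genes that could be named, the chemokine Ccl21 copies had the largest rises in APP/PS1 brain. Ccl21b, a ligand that guides lymphocytes and dendritic cells, rose from a log2 signal of 8.63 ± 0.20 (SD, n = 2) to 13.02 ± 0.06 (SD, n = 3), a 21-fold change. Ccl21c rose 14.8-fold and the related Gm13304 rose 24.4-fold. These copies are near-identical, so the assignment of signal to each copy is uncertain. The mucosal chemokine Ccl28 rose 8.62-fold, with a log2 change of 3.11 ± 0.07 (SE) and a limma adjusted p of 0.000428. Nim1k, a protein kinase gene, and B020031M17Rik lie 3 and 15 positions from Ccl28 in the mouse gene order and rose 3.50-fold and 3.76-fold. Of the measured genes between Ccl28 and B020031M17Rik, Hmgcs1 and Zfp131 had log2 changes of 0.11 and 0.20 that did not pass the threshold, and Tcstv1 fell.

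Smaller rises were measured for Jrkl (1.67-fold), Mia3, which acts in export of collagen from the endoplasmic reticulum (1.54-fold), and Vamp7, a vesicle fusion protein (1.38-fold, named after its value was seen). The testis-type genes Ssty2 and Btbd35f4 were not well above background on either scanned WT array. Ssty2 was at least 1.04-fold higher in APP/PS1, where 2 of 3 arrays measured it, and Btbd35f4 was at least 1.62-fold higher. Both changed sign with another background correction, at log2 changes of -0.30 and -0.17. Mia3 had a log2 change of 0.04 and Nim1k of 0.54 under that correction, neither past the threshold.

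Among named genes that fell, Gm3286, E330014E10Rik and Gm16513, which lie near each other in the gene order, fell by 1.18, 0.99 and 0.67 on the log2 scale. Tcstv1, a gene of the early embryo, fell by 0.88, and Spry3, of the Sprouty family of receptor tyrosine kinase signalling inhibitors, fell by 0.68. The vomeronasal receptor genes Vmn1r241 and Vmn1r135 fell by 0.69 and 0.49, while the other 8 members of that family in the value table did not pass the threshold, 3 of them with no WT array well above background. Gm21953 and the histone variant gene H2al2b fell by 0.53 and 0.41. Tsnax, which encodes the partner of the RNA-binding protein translin, fell by 0.34 with an adjusted p of 0.0243 and had a change of -0.23 with an adjusted p of 0.0972 in the scanner signals. Of the 70 genes with a symbol in the value table, 18 rose, 10 fell and 42 did not pass the threshold.

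**Figure D1:**
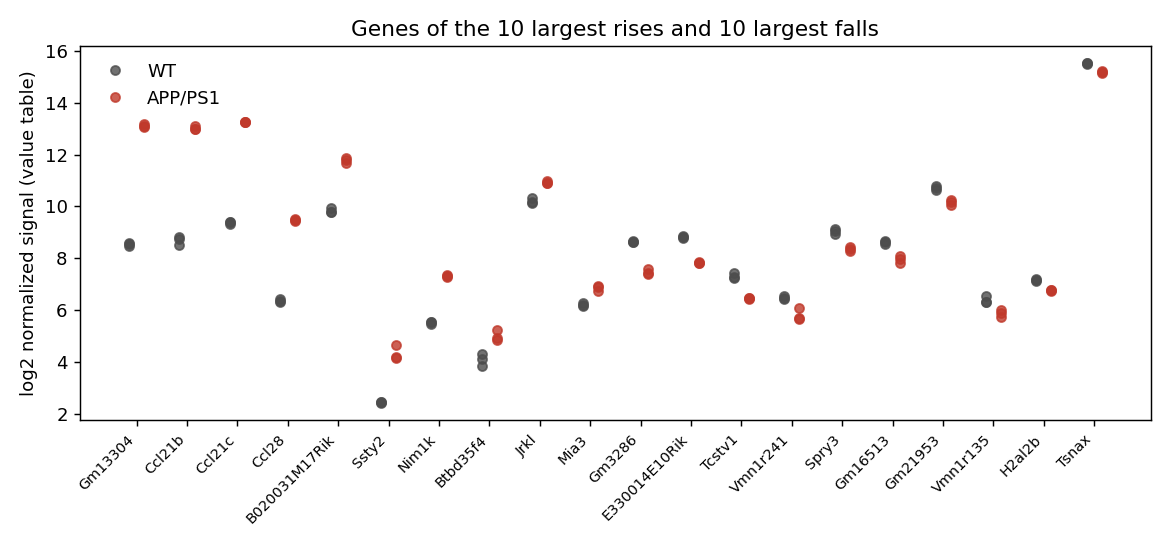
Log2 normalized signal of each sample (points) for the genes with the 10 largest rises and 10 largest falls, WT in grey and APP/PS1 in red, with WT replicates 2 and 3 drawn apart. Ccl21b stood at 8.63 in WT and 13.02 in APP/PS1 on average.

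Across all 48436 probes, 14593 passed an adjusted p of 0.05 in limma, of which 6880 rose and 7713 fell in APP/PS1. The planned fit with WT replicates 2 and 3 apart called 20262. Of the 14593 calls, 1775 rose and 953 fell by at least 2-fold, and 48.5% were changes of less than 1.5-fold. Each column of the value table has a lowest value that several named probes share, 2.41 to 2.44 in WT and 2.32 to 2.37 in APP/PS1. Probes at this floor in every WT sample, such as Ssty2, had almost no spread there (SD 0.02). Their p-values and fold changes rest on the floor, and the 2-fold counts include such probes. The scanned WT arrays lay on slide 1 and the APP/PS1 arrays on slide 2, so slide and genotype cannot be told apart. Leaving out a sample lowered the count to 5725 without WT replicate 1 and to 9139, 7420 and 7663 without APP/PS1 replicates 1, 2 and 3.

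In the scanner signals of the 5 arrays, 8207 probes rose and 6662 fell among 45630 tested, so that 55.2% of the calls were rises against 47.1% in the value table. Of these, 2434 rose and 668 fell by at least 2-fold. The filter also admits probes detected in only 1 genotype, and the APP/PS1 arrays detected more probes. Among probes well above background on all 5 arrays, 7842 rose and 7717 fell, so 50.4% of those calls were rises. The log2 changes of the 45505 probes in both fits correlated at 0.981 across probes, which are not independent replicates. Median centring gave 6001 rises and 7835 falls, and a normexp background correction gave 3377 rises and 4526 falls with a median log2 change of -0.222 over all probes. An offset weighs more on dim probes, and whether it moved this median and balance was not tested. With the replicate number as a block, limma called 0 probes, where 15352 had an unadjusted p under 0.05 and the smallest adjusted p was 0.056 with 1 residual degree of freedom.

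Some probes went from background to clear signal. ASMM9PARTA050454, known here only by the array maker's identifier, was not well above background in WT and at least 121-fold higher in APP/PS1, and ASMM9PARTA039476 was at least 292-fold higher. In the other direction, ASMM9PARTA030909 was at least 50.3-fold lower in APP/PS1, and ASMM9PARTA029273 fell by 6.13 on the log2 scale. In all, 1464 probes were well above background on every APP/PS1 array and no WT array, and 58 showed the opposite; 81 and 18 of these differed by at least 4-fold. The APP/PS1 arrays were also brighter, with median signals of 76.4, 87.1 and 86.7 and 70.2% to 78.5% of probes well above background, against 62.4 and 61.4 and 69.1% and 68.0% on the WT arrays.

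Among probes past the threshold in the value table, those named as long intergenic non-coding RNA (lincRNA) fell more often than they rose. Of 3647 such probes, 328 rose, 650 fell and 2669 did not pass the threshold, so 33.5% of the calls were rises, against 48.1% among other probes (Fisher's exact test, two-sided, p = 5.37e-19, adjusted p = 5.37e-18 over 10 classes). Random probe sets matched on signal gave 48.4%, with 95% of sets between 45.3% and 51.9%. Mouse lincRNA exon probes gave 34.7% rises, mouse lincRNA probes 30.6% and human lincRNA probes 28.0%. In the scanner signals the share of rises was 42.9% for lincRNA probes and 56.0% for other probes, and with normexp it was 16.2% and 44.7%. The normexp offset lowers dim probes on the APP/PS1 arrays. Dim probes were common here: lincRNA probes had a median log2 level of 5.91, against 7.2 for probes with the array maker's identifiers. Above the median level of the value table, 25.6% of lincRNA calls were rises, against 47% of other calls. For probes well above background on all 5 arrays, the shares were 26.3% and 45.7% in the value table. In the scanner signals of such probes they were 32.7% and 51.6%. These values argue against dim probes alone as the source of the lower share. Among calls of at least 2-fold in the value table, 96 lincRNA probes rose and 86 fell, beside 1775 rises and 953 falls over all probes. At an unadjusted p of 0.05 with a 2-fold change, lincRNA probes had the lower share of rises. In the value table it was 52.2% against 64.9% of others (Fisher's exact test, two-sided, p = 0.000149). In the scanner signals it was 74.9% against 79.1% (Fisher's exact test, two-sided, p = 0.131). Rises were also 52.2% of lincRNA calls in the scanner signals without WT replicate 1, against 62.4% of other calls. Probes of 1 transcript are not independent, and all probes were read on the same arrays. The p-values of Fisher's exact tests here and below thus measure spread among probes, not among animals. An effect of the slide, which cannot be told apart from genotype, could give the same values. The files used here do not mark coding probes, so lincRNA probes were compared with all others.

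The share of lincRNA probes called was 26.8%, against 30.4% of other probes (Fisher's exact test, two-sided, p = 5.07e-06), and signal-matched sets gave 26.4%, with 95% between 25.1% and 27.7%. The classes differed: 30.0% of mouse lincRNA exon probes were called, above their matched range of 25.6% to 29.1% and beside 30.1% of all other probes (Fisher's exact test, two-sided, p = 0.93), while 18% of mouse lincRNA probes and 19.3% of human lincRNA probes lay below theirs, 19% to 27.6% and 20.2% to 26.3%. Among probes above the table's median level the difference turned, with 60.9% of lincRNA probes called against 56.4% of others (Fisher's exact test, two-sided, p = 0.00206). At an unadjusted p of 0.05 with a 2-fold change, 6.31% and 6.69% passed (Fisher's exact test, two-sided, p = 0.388).

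Individual lincRNA exon probes changed strongly. MM9LINCRNAEXON10420+, MM9LINCRNAEXON11795+ and MM9LINCRNAEXON11730- were not well above background on the scanned WT arrays and were at least 15.2-fold, 16.1-fold and 5.67-fold higher in APP/PS1. MM9LINCRNAEXON12111- and MM9LINCRNAEXON11100- rose 7.96-fold and 4.65-fold. MM9LINCRNAEXON11325+ was at least 9.98-fold lower in APP/PS1, where no array measured it well above background. MM9LINCRNAEXON10572+, MM9LINCRNAEXON12015-, MM9LINCRNAEXON10138- and MM9LINCRNAEXON10155- fell, with log2 changes of -2.18, -2.17, -1.79 and -1.24.

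**Figure D2:**
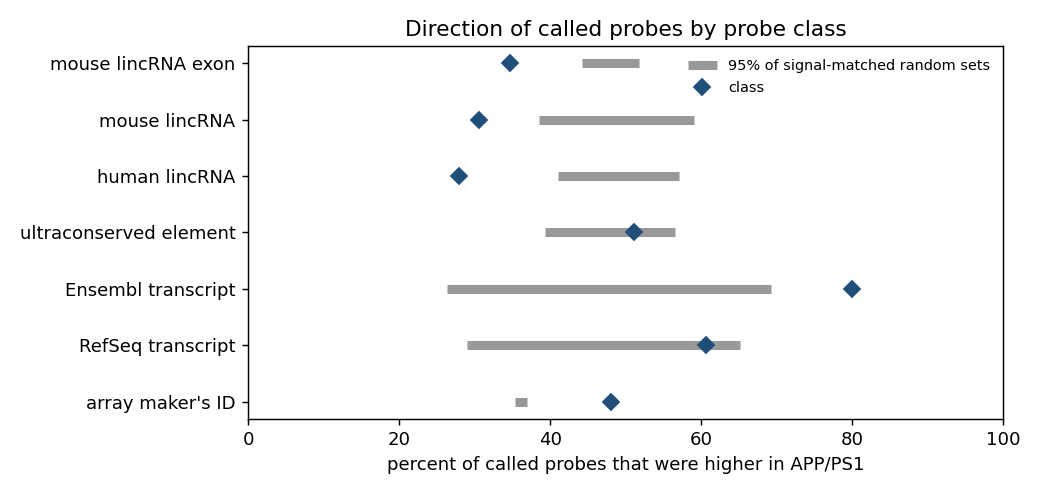
Percent of called probes that were higher in APP/PS1 (x axis) for each probe class (diamonds), with grey bars for 95% of random probe sets matched on signal. Mouse lincRNA exon probes stood at 34.7%, left of their bar.

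Among the fixed lists, B2m, the light chain of major histocompatibility complex class I and a member of the plaque-associated microglia list, rose 1.45-fold in the scanner signals (log2 change 0.54 ± 0.07 SE, limma adjusted p = 0.00743 over all probes). Hmgcs1, a cholesterol synthesis enzyme, had a log2 change of 0.24 ± 0.08 (SE), with a limma adjusted p of 0.083 over all probes, and did not pass the threshold. Each was the only measured member of its list, so no adjustment over the list alone applied. These were the only members of the 26 lists with a probe that could be named, 2 of 520 genes, so no list was tested as a group. No probe carried the symbols App, Prnp or Thy1, so these genes gave no check of the labels.

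B2m was 1 of 15 genes printed as 20 spots per array, all looked at after their values were seen. Among the others, Nono, a nuclear RNA-binding protein of paraspeckles, fell by 0.60 on the log2 scale (adjusted p = 0.00552), and the chaperone Hsp90ab1, Actb and Gapdh fell by 0.33, 0.32 and 0.29. The remaining 10 genes did not pass the threshold, Ppia at -0.01 and Hprt at -0.02. Under the normexp correction Hsp90ab1, Actb and Gapdh had log2 changes of -0.19, -0.15 and -0.15 and did not pass. They passed with larger falls under quantile normalization (-0.48, -0.44 and -0.37) and median centring (-0.41, -0.41 and -0.38). Tuba1b and Tbp passed under quantile normalization (-0.39 and -0.25) but not under median centring. Ppia and Hprt had -0.14 and -0.19 under quantile normalization and did not pass.

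**Figure D3:**
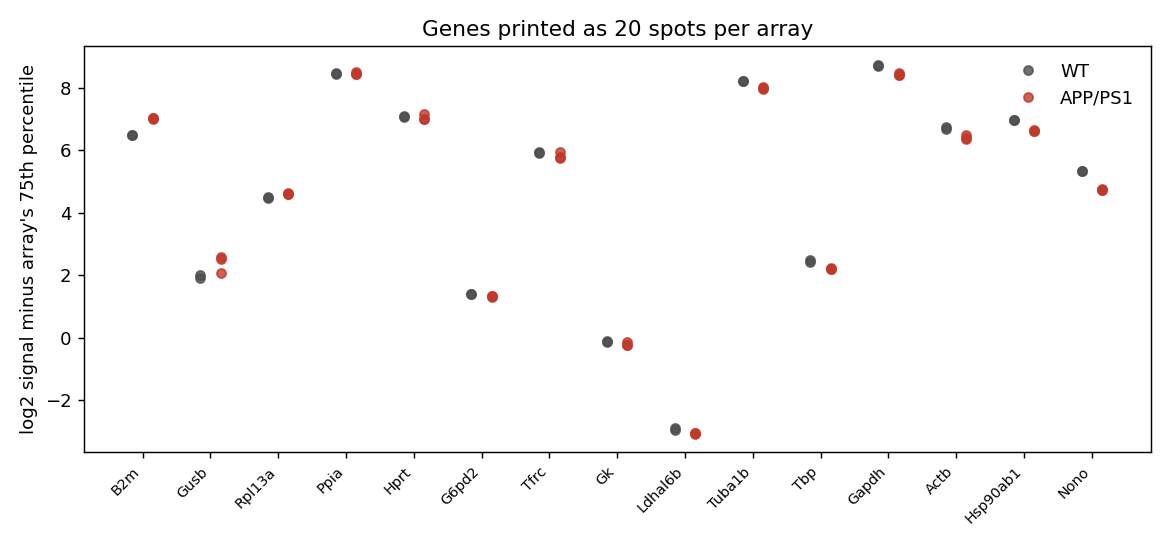
Log2 signal minus the array's 75th percentile (y axis) for the 15 genes printed as 20 spots, 1 point per array for 2 WT (grey) and 3 APP/PS1 (red) arrays. B2m was higher on all 3 APP/PS1 arrays (6.99 to 7.05) than on both WT arrays (6.48 and 6.49).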

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

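The tests on negative controls, slides, other splits and neighbouring genes, and the limits set for the scaling tests, were chosen after the results were seen. Some of the 20 probes named as negative controls, outside the comparisons of the report, gave more signal on the APP/PS1 arrays, while 11 gave less. Of the 5 measured on at least 2 arrays, 4 were higher on every APP/PS1 array than on both WT arrays, with a median shift of 0.68 (log2, range 0.44 to 0.92). Only 1 of them was well above background on all 5 arrays, and choosing probes by detection favours the arrays with more detected probes. The other 15 had a median shift of -0.32, and 9180 ordinary dim probes at the same levels had a median shift of 0.20.

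The count of 14593 probes between genotypes has technical explanations that stay open. Of 14869 calls in the scanner signals, 84.9% were kept in the same direction under median centring and 90.8% under quantile normalization. Median centring moved the median log2 change from 0.037 to -0.0487, little beside the median absolute change of 0.609 among called probes. The kept shares were thus nearly given in advance and do not weigh against scaling as a cause. With normexp, which changes the background, 6766 of the 14869 calls were kept in the same direction. A slide or scan effect may account for part of it, since 0 slides hold both genotypes and the shift of 0.68 in negative controls could come from the slide or from the RNA. The 10 splits of the 6 samples are too few to give a share under 0.05. Only 1 split, the real one, reached 20262 calls, and the highest other gave 1. With WT replicates 2 and 3 as 1 sample, the real split of 10 gave 14593 calls and the highest other 0. Every other split mixes the genotypes within a group, so any large difference between genotypes or slides enters its spread. The low counts of the other splits were thus nearly given in advance and decide nothing about the cause. A genotype effect also remains open, and slide and genotype cannot be told apart in these arrays.

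Large changes lay near each other around Ccl28. Of 6 measured genes spanning 16 positions in the gene order, 3 changed by 2-fold or more in the value table (Ccl28, Nim1k and B020031M17Rik). There Tcstv1 fell by less, and Hmgcs1 and Zfp131 had log2 changes of 0.11 and 0.20. The smallest of the 3 rises over the scalings was 1.79 (log2), though Nim1k had 0.54 under the normexp background correction, which shrinks changes of dim probes. The scalings moved the median change by little, so rises of this size could not be lost, and the result does not weigh against a technical source. A variant of this interval carried by 1 group may be a source, as may the transgenes' effect. The count of 3 decides neither, because these genes were picked for the pattern.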

How the results depend on the processing

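Averaging WT replicates 2 and 3 and normexp on the median signal were chosen after seeing the data. In the value table, the count of 14593 stayed within 1.5 times under scaling, filters, variance model and the replicate block (15417 with WT replicates 2 and 3 apart); an unadjusted p with a 2-fold change gave 3226, and leaving out 1 sample gave 5725 to 14380. The table's columns are already equal in distribution, so recentring moves little. In the scanner signals, the count of 14869 became 7903 with normexp, 0 with the replicate block, which leaves 1 residual degree of freedom, and 3563 at an unadjusted p with a 2-fold change; leaving out 1 sample gave 7594 to 10465. A lone WT sample was assumed to vary like the other group.

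The difference in the share of probes called between lincRNA and other probes, -3.58 percentage points, turned to 4.54 among probes over the table's median level. It lost its call at -0.265 among probes well above background on all 5 arrays and at -0.383 with the 2-fold threshold. In the scanner signals it lost its call at -0.978 (normexp), -0.406 (median centring), -1.73 (probes well above background on all arrays) and -0.000801 (2-fold threshold). Leaving out 1 sample gave -3.56 to -2.17 in the value table and -2.07 to 0.331 in the scanner signals, the last without WT replicate 2. The cause of these moves was not tested; sets matched on signal were called at 26.4%, against 26.8% of lincRNA probes.

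Of 861 values of 56 named probes under other settings, 782 kept direction and side of the threshold, 66 lost the call, 6 gained it and 7 changed sign; with 1 sample left out, 449 of 521 kept both. Signs changed with normexp for Ssty2 (-0.30), Btbd35f4 (-0.17), Ppia (0.14), G6pd2 (0.01), Hprt (0.12) and Tfrc (0.02), and with the replicate block for Ppia (0.00); none of the last 4 genes passed the threshold. With 1 sample left out, Ppia ranged from -0.03 to 0.00 and Hprt from -0.07 to 0.00. The gene list and transgene alternatives were not run, because no list had 5 named members, nor was the slide block, because each slide held 1 genotype. By level, 15.1% of probes under a log2 level of 5 were called, against 40.5% between 8 and 10, while 8.25% and 5.19% were called with a change of at least 2-fold.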

Other observations

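Ultraconserved elements, stretches of genome identical between distant mammals, gave 70 rises and 67 falls among 510 probes, so 51.1% of the calls were rises, against 63.7% of 146 calls in the scanner signals. These elements were named after their values were seen. The probes of both strands of uc.430 were higher in APP/PS1: uc.430- rose 23.9-fold, with 1 of the 2 scanned WT arrays well above background, and uc.430+ was at least 2.45-fold higher, with no WT array well above background. In the other direction uc.308- fell by 1.79 on the log2 scale. Transcripts with Ensembl identifiers mostly rose where they changed, 16 against 4 of 67, and 80.8% of their calls were rises in the scanner signals (adjusted p for direction 0.00656 over 10 classes in the value table).

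Whether both strands of an element change together was then tested, with the prediction written before the result. Across 505 mouse lincRNA exons with both probes well above background, the log2 changes of the + and - probes correlated at 0.0598, and 78 of 1000 random pairings were as high, so shared signal from both strands is not seen in this class. Across 65 such ultraconserved elements the correlation was 0.218, and 43 of 1000 random pairings were as high. Elements are not independent replicates.

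Gusb, 1 of the genes printed as 20 spots, stood at 2.58, 2.53 and 2.07 (log2, relative to the array's 75th percentile) on the APP/PS1 arrays and at 1.91 and 2.00 on the WT arrays, with a mean SD between its spots of 0.09.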
